A study of Mus musculus with 3 samples.

How the data were processed

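Total RNA from embryoid bodies of day 7 was labelled from 6 ug per sample and hybridized to Affymetrix mouse expression arrays, 1 array for each of the WT, MI and RQ genotypes, per the labels. Feeder cells were removed on gelatin-coated plates before the bodies were formed from the unattached stem cells, and the medium was first changed on day 3, per the labels. The values used here are the deposited log2 signals of 45101 probe sets per array. Partek and RMA are named in the submitters' processing notes, without versions and without the order of steps. RMA is a method that subtracts background, makes the distributions of arrays alike and summarises the probes of each set. The mean and quartiles of the 3 deposited columns were close but not identical, so whether the arrays were normalized together with others is not given in the sources used here. Scanner files, detection calls and scan dates were not used here, so no probe set could be called absent and no batch could be examined. Signals near the level filter are compressed towards background, and differences against a low signal can understate the true ratio.

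Probe sets were named from the platform annotation supplied for the series. Of the 45101 probe sets, 34958 had 1 gene symbol, 932 had several and 9211 had none or were not listed. The 64 control probe sets were kept apart, which left 34945 probe sets of 18193 genes. Entrez identifiers of 34754 probe sets matched the RefSeq gene table of assembly GRCm38.p6, which was used for names alone and changed 0 symbols. No genome build is named for the arrays, so no coordinates are given. For the 9010 genes with more than 1 probe set, the probe set with the highest mean over the 3 arrays was used.

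Differences are of log2 values on 2 arrays, with the direction given. With 1 array per genotype no test across genes was run and no p-value is given. Genes were counted at a 2-fold limit among those whose higher value reached the median of all probe sets over the 3 arrays (log2 6.31). A total of 34 gene lists with 671 entries, of which 617 had a gene on the arrays, was written before the data were examined. They cover pluripotency, epiblast, primitive streak, definitive endoderm and gut, visceral endoderm and yolk sac, parietal endoderm and basement membrane, trophoblast, blood, endothelium, heart, paraxial mesoderm, neural cells, neural crest, fibroblasts and mesenchyme, smooth muscle, Hox and Cdx genes and germline. They also cover p53 targets, homologous recombination and BRCA1 complexes, G2/M, G1/S, miR-155 targets from the literature, interferon response, NF-kB and inflammation, histone deacetylases, hypoxia and glycolysis, cholesterol synthesis, amino acid and unfolded protein stress, imprinted genes, Wnt targets, BMP targets, ribosomal proteins, mitochondrial respiration, and Y-linked genes with Xist. Each list is described by its median difference and the percentile of that median among 10000 random lists of the same size, matched in 20 bins of mean level, which describes these arrays and is not a test of genotype.

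The genes named in the text were chosen by a rule fixed before the data were examined. It takes Brca1 and Mir155hg, and the 12 highest and 12 lowest genes of each mutant against WT and the 6 highest and 6 lowest of RQ against MI, among genes above the filter whose other probe sets above the filter differed the same way. It also takes the 5 genes per array and direction that stood farthest apart from both other arrays, and up to 4 members of each list with the largest difference. Genes named beyond the rule are said to have been chosen after their values were seen. Members of a list given as at least 2-fold higher or lower are part of the list's count.

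Because both mutants are compared with the same WT array, their correlation and overlap were set beside those of 100 shuffles of the 3 arrays within each gene and beside the overlap of independent lists. Alternatives chosen before the data were examined were centring arrays on their medians, quantile normalization again, a lowess correction of each difference on mean level (span 0.3, 3 robustness iterations), no level filter, a filter at the 75th percentile (log2 6.92), the mean of a gene's probe sets, leaving out probe sets that can match several transcripts, limits of 1.5-fold and 3-fold, counting genes with probe sets in the same direction, and list means. Hybridization spikes and the 3' and 5' control probe sets of Actb and Gapdh were read as checks of the arrays. The 3' minus 5' difference of Actb was 0.64 in WT, 0.78 in MI and 0.52 in RQ, and that of Gapdh was 0.12, 0.05 and 0.11. The 18 spike probe sets, which read the transcripts bioB, bioC, bioD and cre, were lower on both mutant arrays than on the WT array. The median difference was -0.64 in RQ (-1.38 to -0.42) and -0.80 in MI (-1.48 to -0.36). Some of these controls thus lay past 2-fold below WT in both mutants.

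The counting was tested on simulated data made from the mean level of the 18193 genes with noise of SD 0.2. For RQ against WT, 97.0% of 100 genes changed by 1.5 on the log2 scale and 100% of 100 genes changed by 2.5 were called in the right direction, and 5 unchanged genes were called. The changed genes were drawn from those at least 1 log2 unit above the level filter. The noise was set for each array and not measured, and the observed SD of RQ minus WT across genes above the filter was 0.41. The 5 calls are therefore no estimate of false calls on the real arrays. Of 200 random unmoved lists in that simulation, 5.00% lay outside the central 95%. A level-dependent shift of -0.30 put into the abundant genes of a simulated MI array against WT became 0.00 after the lowess correction. Calculations used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, statsmodels 0.14.6 and matplotlib 3.10.9.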

Results

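Embryoid bodies are clusters of embryonic stem cells that start to differentiate in suspension and form cells of the early germ layers and of the extraembryonic endoderm. The data are messenger RNA levels in embryoid bodies of mouse strain 129S7 embryonic stem cells collected on day 7, which carried wild-type human BRCA1 (WT) or human BRCA1 with a single substitution. BRCA1 is a tumour suppressor that acts in repair of DNA breaks by homologous recombination. The substitution in the MI bodies is M1652I, and the RQ bodies carry R1699Q according to the series design, although the label of that array gives the position as R1669Q. Each of the 3 genotypes was measured on 1 Affymetrix mouse expression array with 45101 probe sets, so there are no replicates, no difference given here has a replicate check, and the number of arrays limits the precision. Differences are therefore described as higher or lower on these arrays. The mean log2 signal was 6.60 on each array, with a median of 6.29 for WT, 6.35 for MI and 6.28 for RQ. The spread over probe sets was smaller on the MI array (SD 1.06) than on the WT and RQ arrays (both SD 1.17). Pearson's r across probe sets was 0.964 for RQ with WT, 0.965 for MI with WT and 0.968 for RQ with MI. Probe sets of 1 array are not independent replicates.

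The targeted gene gave no check of the labels. The arrays carry probe sets for mouse Brca1, which are not known to read the human gene the cells were given. The chosen Brca1 probe set read 6.81 in WT, 6.96 in MI and 6.80 in RQ, and the 4 Brca1 probe sets differed from WT by -0.26 to 0.03 in RQ and by -0.52 to 0.15 in MI. Mir155hg, the host gene of miR-155, read 5.36 in WT, 5.34 in MI and 5.29 in RQ. It lay below the level filter of 6.31 on each array, so its differences were not read.

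The first comparison asks how the bodies with the RQ variant differed from those with wild-type BRCA1. Among the largest differences were those of several endodermal and basement membrane genes, which were lower in RQ. Cubn, the endocytic receptor cubilin of the yolk sac endoderm, was 23.9-fold lower (log2 10.67 in WT and 6.09 in RQ), and Lama1, a laminin chain of the earliest basement membranes, was 15.5-fold lower (9.93 and 5.98). Sparc, a matrix protein that parietal endoderm makes in large amounts, was 14.4-fold lower (12.37 and 8.52). In the other direction, genes known from embryonic stem cells were higher in RQ. Dppa2, a chromatin factor of pluripotent cells, was 8.97-fold higher (7.38 and 10.55), and L1td1, an RNA-binding protein of pluripotent cells, was 7.82-fold higher (7.15 and 10.12).

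Among 12226 genes above the level filter, 205 were at least 2-fold higher and 182 at least 2-fold lower in RQ than in WT. Besides Dppa2 and L1td1, the 12 highest were Manba, which encodes the lysosomal enzyme beta-mannosidase (log2 difference 3.33), the germline gene Tex19.1 (2.35), the transcription factor Klf9 (2.14), the corepressor Tle4 (2.13), Zmym1 (1.99), the junctional adhesion gene Jam2 (1.98), Lrr1 (1.95), the pluripotency marker Zfp42 (1.93), the ETS factor Etv5 (1.92) and Nr0b1 (1.92), a nuclear receptor of embryonic stem cells. Besides Cubn, Lama1 and Sparc, the 12 lowest were the proteoglycan gene Srgn (-4.49), Gja1, which encodes connexin 43 (-3.51), the type IV collagen chain Col4a2 (-3.46), the endocytic adaptor Dab2 (-3.44), the epithelial keratins Krt18 (-3.31) and Krt8 (-2.98), the Y-linked Eif2s3y (-3.26), the carbonic anhydrase Car4 (-3.24) and the protease inhibitor Spink1 (-2.95). The 4 probe sets of Dab2 ranged from -3.44 to -0.64, and without those that can match several transcripts its difference was -0.64. With the mean of each gene's probe sets the differences were 1.09 for Klf9, 1.01 for Tle4, 1.004 for Jam2, 1.12 for Lrr1, -2.04 for Gja1, -2.71 for Sparc and -1.76 for Eif2s3y. Without probe sets that can match several transcripts, Cubn was at -3.60, Dppa2 at 2.53 and Gja1 at -2.79.

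Of the pluripotency list, 11 of 26 genes were at least 2-fold higher in RQ than in WT and 1 was 2-fold lower. The list's median difference of 0.70 lay at percentile 100 of 10000 random lists matched on level. Dppa2, Zfp42, Nr0b1 and Klf2 (1.68) led it. The exception was Lin28a, an RNA-binding protein of early embryonic cells, with a difference of -1.47. Other core factors, named here after their values were seen, were not alike, since Nanog (1.67), Klf4 (1.24) and Sox2 (1.23) were higher while Pou5f1 (-0.14) and Dppa5a (-0.15) were close to WT. Of the epiblast list (median 0.17), Nodal was higher (1.15), Dnmt3a differed by 0.75, Zic2 by 0.55 and Dnmt3b by -0.78.

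Of the parietal endoderm and basement membrane list, 7 of 12 genes were at least 2-fold lower in RQ, and the median difference was -1.68 (percentile 0). Col4a1 (-2.84) joined Lama1, Sparc and Col4a2, and the others were Lamb1, Lamc1 and Hspg2. All 7 encode laminins, type IV collagens or other matrix proteins. No other member of the list, which also holds Thbd, Plat, Fst, Snai1, Pdgfra, Stra6 and Nid1, was read as 2-fold lower. Of the visceral endoderm and yolk sac list, 5 of 13 genes were at least 2-fold lower, with a median of -0.15 (percentile 0.54) and a mean of -1.13. They included Cubn, Dab2, Lrp2 (-2.59), which encodes megalin, and Amn (-1.59), the partners of 1 endocytic receptor complex. Secreted products of this tissue gave no such reading, since none of the 13 on the array, such as Afp, Ttr and Apoa1, lay 1 log2 unit above the filter in WT. Of the definitive endoderm and gut list, 4 of 12 genes were at least 2-fold lower (median -0.22, percentile 0.13), namely Spink1, the claudins Cldn6 (-2.06) and Cldn4 (-1.62), and the keratin Krt19 (-1.01). The visceral endoderm median was -1.59 with the stricter filter, and the gut median was -0.94 with that filter and -0.11 without a filter. The smooth muscle list had a median of -0.56 (percentile 0), with Tagln at -1.36, Acta2 at -0.75, Tpm1 at -0.63 and Tpm2 at -0.56, and a median of -0.24 without the level filter and -0.35 with means of probe sets.

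In the G1/S list 22 of 24 genes were above 0 in RQ against WT (median 0.39, percentile 100), with the ribonucleotide reductase subunits Rrm1 (1.02, and 0.99 after the lowess correction) and Rrm2 (0.91), Gins1 (0.88) and Cdc6 (0.77) at the top. The list of homologous recombination genes and BRCA1 complexes had a median of 0.29 (percentile 99.8), with 16 of its 22 genes above 0, 6 below and none past 2-fold, and the median was 0.15 without the level filter. Exo1 (0.88), Brca2 (0.83), Rad54l (0.70) and Palb2 (0.68) led it. The G2/M list (median 0.13) and the p53 target list (median 0.10, percentile 85.3) lay within the central 95% of random lists, with Kif11 at 0.74, Cenpf at 0.71 and Cdk1 at 0.58 in the former, and Gadd45a at 0.81, Trp53inp1 at 0.68 and Btg2 at -0.59 in the latter. As Mir155hg lay below the level filter on each array, miR-155 itself was not read. The miR-155 target list, which was included because BRCA1 has been linked to repression of miR-155, had a median of 0.32 (percentile 99.96). This median lay above 0, with 13 members above and 9 below, whereas lost repression of miR-155 would lower its targets. The list's members did not move as a block, since Jarid2 (1.20) and Msh6 (1.05) were at least 2-fold higher, Myo10 differed by 0.96 and Fos was lower (-1.42). The median was 0.08 without the level filter, 0.52 with the stricter filter and 0.44 with means of probe sets.

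Among metabolic and signalling lists, cholesterol synthesis was lower in RQ, with 13 of 15 genes below 0 and a median of -0.42 (percentile 0.01). Insig1, a sterol-regulated inhibitor of the pathway, differed by -1.77, Stard4 by -0.84, Fdft1 by -0.67 and Dhcr7 by -0.60, and the median was -0.22 with means of probe sets and -0.27 without probe sets that can match several transcripts. The imprinted list had a median of -0.11 (percentile 1.90) and was led by the noncoding RNA gene Meg3 (-2.26), Cdkn1c (-0.94), Grb10 (-0.92) and Igf2 (-0.72). Each of the 18 ribosomal protein genes measured was below 0, by small amounts (median -0.22, percentile 1.65), such as Rpl27 (-0.37), Rpl11 (-0.32), Rps19 (-0.32) and Rps9 (-0.29), and the median was -0.08 after the lowess correction and -0.06 after quantile normalization again. The list of amino acid and unfolded protein stress had a median of -0.15 (percentile 0.80) with a mean of 0.02, and held Ddit3 (-1.37), Xbp1 (1.03), Shmt2 (0.95) and Asns (0.95). The hypoxia and glycolysis list (median -0.12, 4 genes 2-fold higher and 2 lower) split between Pdk1 (1.30) and Egln3 (1.28) on the higher side and P4ha1 (-1.52) and Aldoc (-1.22) on the lower side. Of these list members, Xbp1 was at 0.17 and Aldoc at -0.22 without probe sets that can match several transcripts. With means of probe sets Rrm1 was at 0.30, Pdk1 at 0.76, Lrp2 at -1.25 and Meg3 at -1.27.

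The other lists lay within the central 95% of random lists for RQ against WT. Median differences were 0.09 for germline, with Tex19.1, Stra8 (1.69) and Dazl (1.36) at least 2-fold higher and Sycp3 at -0.94, and 0.16 for Wnt targets, -0.01 for BMP targets (mean 0.01) and 0.01 for interferon response genes (mean -0.35), where B2m, the light chain of MHC class I, was the only gene past 2-fold (-2.56). They were -0.09 for NF-kB and inflammation genes, 0.02 for mitochondrial respiration genes and -0.00 for histone deacetylases (mean 0.14), in which Sirt1 was higher (1.20). For markers of other cell types they were 0.02 for primitive streak, -0.04 for trophoblast (mean 0.12, Tfap2c 1.10), -0.03 for blood, 0.04 for endothelium (mean -0.01), -0.01 for heart, -0.06 for paraxial mesoderm (Tcf15 1.05), -0.09 for neural cells, 0.08 for neural crest, -0.05 for fibroblasts and -0.04 for Hox and Cdx genes. Most of these markers lay near the level filter. Of the Y-linked and Xist list, 3 genes could be read (median 0.06, mean -1.04). Eif2s3y was 8.56 in WT, 6.31 in MI and 5.30 in RQ, while its second probe set lay below the filter on each array. Uty (0.06) and Xist (0.09) were close to WT. The 4 Uty probe sets differed by -0.31 to 0.06 in RQ, and all but the probe set used lay below the filter. Uty therefore does not show whether other Y-linked genes were unchanged.

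**Figure D1:**
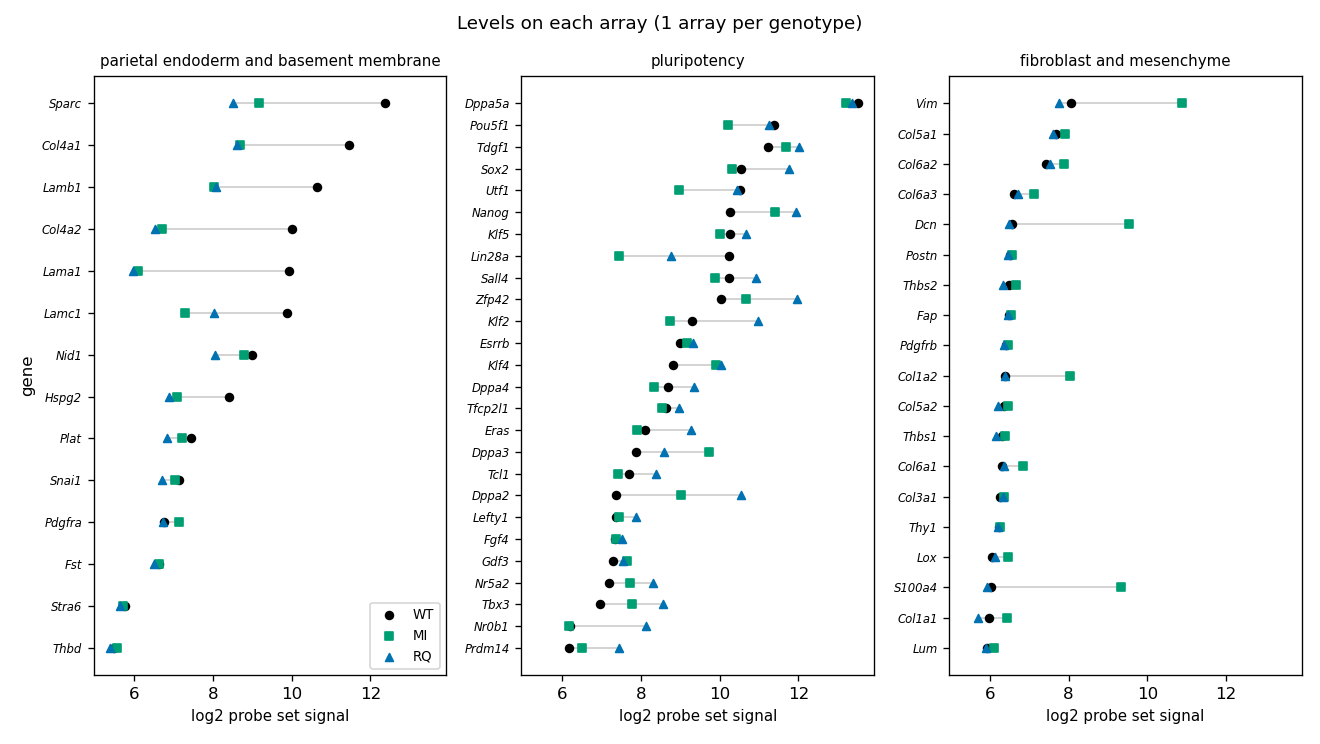
Log2 probe set signal of each member of the parietal endoderm and basement membrane, pluripotency, and fibroblast and mesenchyme lists on the WT (circles), MI (squares) and RQ (triangles) arrays, 1 array each, with a line from the lowest to the highest value. Sparc, at 12.37 in WT, was lower in both mutants, Zfp42 was highest in RQ at 11.97, and Dcn was highest in MI at 9.54.

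The second comparison asks the same of the MI variant. Cubn (24.2-fold), Lama1 (14.2-fold) and Sparc (9.26-fold) were lower in MI than in WT, as they were in RQ, whereas Rhox5 of the visceral endoderm list differed by -1.54 in RQ and 0.66 in MI. Of the 12 highest genes, Tex19.1 was also among the 12 highest in RQ and the others were not. S100a6, a calcium-binding protein of mesenchymal and proliferating cells, was 14.0-fold higher than in WT (log2 6.56 in WT and 10.36 in MI), Dcn, which encodes the matrix proteoglycan decorin, was 7.81-fold higher (6.57 and 9.54), and Vim, the intermediate filament of mesenchymal cells, was 7.13-fold higher (8.05 and 10.89). Dcn read 6.48 and Vim 7.75 in RQ.

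Among 12786 genes above the level filter, 66 were at least 2-fold higher and 312 at least 2-fold lower in MI than in WT. The 12 highest, besides S100a6, Dcn and Vim, were S100a4 (3.31), the hyaluronan receptor Cd44 (3.27), Anxa1 (3.14), the imprinted gene Dlk1 (3.13), the adhesion molecule Vcam1 (2.81), cyclin D1 (Ccnd1, 2.69), Cpe (2.59), the proteoglycan Bgn (2.48) and Tex19.1 (2.30). The 12 lowest, besides Cubn, Lama1 and Sparc, were Srgn (-4.74), the lipid carrier Apoe (-3.65), Car4 (-3.34), Col4a2 (-3.30), Krt18 (-3.24), the lysosomal reductase Ifi30 (-3.15), the lysosomal protease Lgmn (-2.98), Spink1 (-2.96) and Dab2 (-2.86). The value of Dlk1 rests on a probe set that can match several transcripts, and its other probe set, below the level filter, differed by 0.18. With the mean of each gene's probe sets, which includes those with little signal, the differences were 1.66 for Anxa1, 1.71 for Cd44, 1.36 for Vcam1, 1.58 for Cpe, 1.35 for Bgn, 1.94 for Ccnd1, 1.53 for Dcn, -2.29 for Sparc and -1.48 for Dab2. Without probe sets that can match several transcripts, Cubn was at -3.58 and Dab2 at -0.49, short of 2-fold. The balance of these counts depends on scaling, because genes above a level of 8 were generally lower on the MI array (median difference -0.35 at levels of 9 to 10), while the median at levels of 6 to 7 was 0.10. With a lowess correction for level the counts were 79 higher and 225 lower, and with the arrays quantile-normalized again they were 107 and 193.

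**Figure D2:**
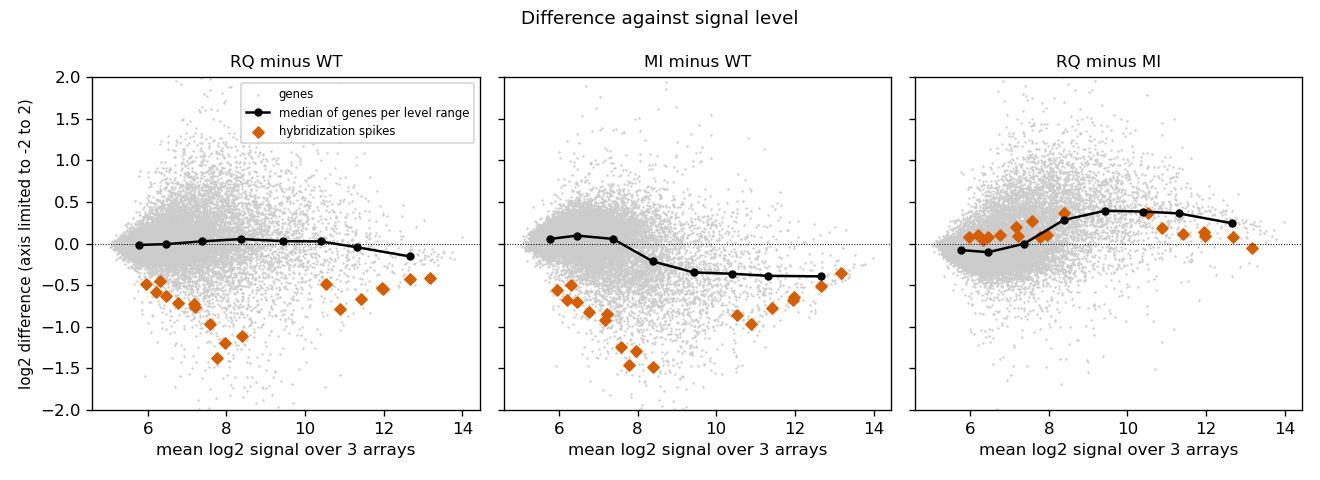
Log2 difference (y axis, limited to -2 to 2) against the mean log2 signal of the 3 arrays (x axis) for RQ minus WT, MI minus WT and RQ minus MI, with genes in grey, medians per level range in black and hybridization spikes as diamonds. At levels of 10 to 11 the median was -0.36 for MI minus WT and 0.03 for RQ minus WT.

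The fibroblast and mesenchyme list had a median difference of 0.39 in MI (percentile 100), and 4 of its 17 genes were at least 2-fold higher, namely S100a4, Dcn, Vim and Col1a2 (1.64). Each of the 17 was above 0 against WT, and each was lower in RQ than in MI. Only 14 members passed the filter for RQ against WT, so some were read through their MI signal alone. Matched random lists had a median of 0.09 for MI against WT, and the list's median was 0.29 after the lowess correction. The differences of the members short of 2-fold included those of Col1a1 (0.46, at 6.43 in MI) and Col3a1 (0.09, at 6.35 in MI), which lay close to the filter. Both were named after their values were seen, and the other probe set of Col3a1, below the filter, differed by 0.48. The median was 1.64 with the stricter filter and 0.21 without a filter. The stricter filter reads the higher of the 2 arrays, so members such as Dcn pass it through MI alone. Its median can therefore be raised by the choice of members. The NF-kB and inflammation list (median 0.32, percentile 100) held Vcam1, Cxcl1 (2.24), Nfkbia (0.63) and Ccl2 (0.45), and the interferon response list (median 0.32, percentile 100) held Usp18 (1.24), Oas1a (0.99), B2m (0.84) and Oasl2 (0.68). Without the level filter these medians were 0.17 and 0.21, and with the stricter filter the interferon median was 0.68. The germline list (median 0.27, percentile 99.7) was led by Tex19.1, Dazl (1.55) and Slc25a31 (1.11), with Sycp3 at -0.68, and its median was 0.16 without the filter and 0.56 with the stricter filter. The neural crest list (median 0.25, percentile 99.0; Mitf 0.44 and Tfap2a 0.38) and the trophoblast list (median 0.25, percentile 98.2; Esx1 0.55 and Tfap2c 0.32) were slightly above their matched lists, and no gene of either reached 2-fold. The neural crest median was 0.17 with means of probe sets, and the trophoblast median was 0.12 without the filter and 0.16 without probe sets that can match several transcripts.

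Pluripotency genes were mixed in MI. Of 25 measured, 4 were at least 2-fold higher than in WT and 3 at least 2-fold lower, with a median of 0.01, which changes sign with the processing, against -0.23 for level-matched lists (percentile 97.52). It was 0.16 after the lowess correction and 0.19 after quantile normalization again. Dppa3, a marker of naive cells and germ cells, was higher (1.86) together with Dppa2 (1.64), and Lin28a (-2.80) and Utf1 (-1.56) were lower. Pou5f1 (-1.17) and Nanog (1.14), named after their values were seen, differed in opposite directions, and the lowess-corrected value of Pou5f1 was -0.77. The epiblast list had a median of -0.08, with Dnmt3b at -1.70, Otx2 at -1.37, Pim2 at -0.55 and Nodal at 0.35.

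The parietal endoderm and basement membrane list had a median of -1.95 in MI (percentile 0), which was -0.78 without the level filter. Of its 12 genes, 7 were at least 2-fold lower, the same matrix genes as in RQ, with Col4a1 (-2.78) among them, and 2 were above 0. Of the visceral endoderm list, 4 of 16 genes were at least 2-fold lower, namely Cubn, Dab2 (on the probe set used), Lrp2 (-2.37) and Amn (-1.47), and the median was 0.09 (percentile 43.0) with a mean of -0.60. Of the definitive endoderm and gut list, 4 of 12 genes were at least 2-fold lower (median -0.35, percentile 0.06), which were Spink1, Cldn6 (-2.20), the epithelial adhesion gene Epcam (-1.97) and Cldn4 (-1.46). That median was -1.11 with the stricter filter and -0.03 without a filter. The cholesterol synthesis list had a median of -0.66 (percentile 0.01), with Insig1 (-1.87), Msmo1 (-1.05) and Stard4 (-1.03) at least 2-fold lower and Hmgcs1 at -0.86. Stard4 was at -0.93 after the lowess correction, and the median was -0.37 with means of probe sets. Smooth muscle genes had a median of -0.32 (percentile 1.82; Tagln -1.24, Des -0.41), which was -0.125 after quantile normalization again, -0.137 without the filter and -0.106 with means of probe sets. The G2/M list had a median of -0.50 against -0.24 for matched lists (percentile 1.43), with Nusap1 (-1.05) and Ube2c (-1.03) lowest. After the lowess correction that median was -0.35 and these genes were at -0.80 and -0.65, short of 2-fold, and the median was -0.30 after quantile normalization again and -0.28 with means of probe sets. With means of probe sets Nusap1 was at -0.42 and Ube2c stayed at -1.03. The imprinted list had a median of -0.17 (percentile 2.18) although Dlk1 and Plagl1 (1.35) were higher, beside Meg3 (-1.47) and Grb10 (-1.10), and its median was -0.05 after quantile normalization again.

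The other lists lay within the central 95% for MI against WT. The homologous recombination list had a median of 0.13 (percentile 94.8; Blm -0.56, Brca2 0.52), p53 targets -0.01 (Bbc3 -0.70, Ei24 -0.67), G1/S -0.11 (Gins1 1.34, Uhrf1 -1.11) and miR-155 targets 0.03 (percentile 64.0; Fos -1.15, Rhoa -0.85, mean -0.05). The medians were -0.35 for hypoxia and glycolysis (Pfkl -1.56, P4ha1 -1.44), -0.44 for ribosomal proteins, -0.37 for mitochondrial respiration and -0.23 for histone deacetylases. Matched lists had medians of -0.24, -0.31, -0.35 and -0.02 in the same order. Stress genes had a median of -0.16 (Ddit4 -1.25), Wnt targets 0.04 with Ccnd1 as the member that differed most, and BMP targets -0.01 (mean 0.05). Cell type markers had medians of 0.17 for primitive streak, 0.09 for blood, 0.04 for endothelium (mean -0.03), 0.17 for heart (Ttn 0.63), 0.15 for paraxial mesoderm, 0.11 for neural cells (Stmn2 -1.23, mean -0.02) and 0.12 for Hox and Cdx genes. The Y-linked and Xist list had a median of 0.22 and a mean of -0.58, with Eif2s3y at -2.25. Without probe sets that can match several transcripts, Col1a2 was at 0.49, Plagl1 at 0.16, Pfkl at -0.16, Msmo1 at -0.33 and Cxcl1 at 4.36. With means of probe sets Lrp2 was at -1.14, Epcam at -0.97, Gins1 at 0.76, Meg3 at -0.76, Utf1 at -0.61 and Grb10 at -0.41.

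**Figure D3:**
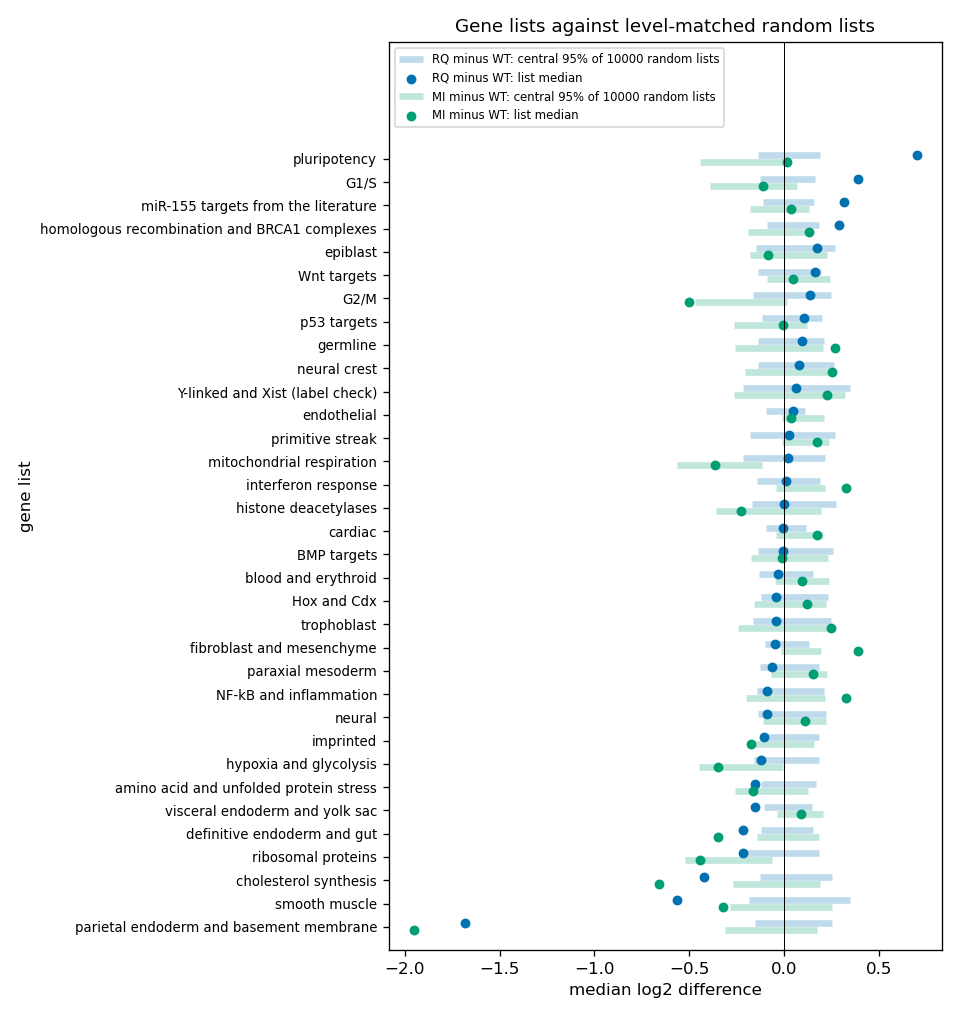
Median log2 difference of each of the 34 gene lists for RQ minus WT (blue points) and MI minus WT (green points), with bars for the central 95% of 10000 random lists matched on signal level. The pluripotency median was 0.70 in RQ, and the parietal endoderm and basement membrane medians were -1.68 in RQ and -1.95 in MI.

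The mutants were also compared with each other. RQ was above MI for Manba (9.90-fold), Ifitm1, an interferon-inducible membrane protein also found in early embryos (5.33-fold), and Elob, an elongin subunit (5.22-fold), followed by Klf2 (2.24), Etv5 (2.10) and the Hedgehog receptor Ptch1 (4.01-fold, or a log2 difference of 0.67 with the mean of its probe sets). RQ was below MI for S100a6 (18.0-fold), S100a4 (10.6-fold), B2m (10.5-fold), Cd44 (10.5-fold), Dlk1 (10.5-fold, with -0.08 on its other probe set) and Anxa1 (9.53-fold). With means of probe sets the log2 differences were -1.77 for Cd44, -1.73 for Dlk1 and -1.68 for Anxa1. Pluripotency genes were higher in RQ than in MI (median 0.85, 11 of 26 at least 2-fold higher and Dppa3 lower at -1.15), as were those of the epiblast (median 0.45; Otx2 1.54, Dnmt3a 1.09), of G2/M (median 0.64; Nusap1 1.18) and of G1/S (median 0.50; Pola1 1.27, Mcm2 1.12). After the lowess correction these 4 medians were 0.63, 0.49, 0.33 and 0.23, and the genes still at least 2-fold higher were 7 of 11 for pluripotency, 1 of 2 for the epiblast (Dnmt3a 0.92), 0 of 1 for G2/M (Nusap1 0.87) and 1 of 3 for G1/S (Mcm2 0.78). With the stricter filter the epiblast median was 0.80. With means of probe sets Pola1 was at 0.63, Dnmt3a at 0.67, Nusap1 at 0.45 and Bach1 of the miR-155 list at 0.46. The miR-155 targets had a median of 0.27 (Jarid2 1.36, Bach1 1.24) and the histone deacetylases 0.46, with lowess-corrected medians of 0.18 and 0.10 and medians of 0.0088 and 0.06 without the level filter. The miR-155 median was 0.11 after quantile normalization again, 0.60 with the stricter filter, 0.45 with means of probe sets and 0.40 without probe sets that can match several transcripts. On the lower side in RQ were interferon response genes (median -0.36; Usp18 -1.22), NF-kB and inflammation genes (median -0.35; Vcam1 -2.84, Cxcl1 -2.33) and fibroblast and mesenchyme genes (median -0.33; Dcn -3.06). With the stricter filter, which members such as Dcn pass through MI alone, the interferon and fibroblast medians were -0.64 and -1.64. The NF-kB median was -0.55 without probe sets that can match several transcripts. Cxcl1 was at -4.55 without such probe sets. With means of probe sets Vcam1 was at -1.43, Cxcl1 at -2.89 and Dcn at -1.58. Lower by less were parietal endoderm (median -0.21), visceral endoderm (-0.22), smooth muscle (-0.24), neural crest (-0.22), trophoblast (-0.235) and imprinted genes (-0.15), each below the central 95% of random lists. After the lowess correction the visceral endoderm and trophoblast medians were -0.11 and -0.145, and with centred arrays those of parietal endoderm, neural crest and imprinted genes were -0.13, -0.14 and -0.05. The smooth muscle median was -0.104 without the filter and -0.089 without probe sets that can match several transcripts. Median and mean differed in sign for definitive endoderm and gut (-0.11 and 0.08), endothelium (-0.02 and 0.02), Wnt targets (0.01 and -0.22) and BMP targets (0.01 and -0.04).

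In counts, 253 of 12800 genes were at least 2-fold higher and 65 at least 2-fold lower in RQ than in MI. This balance again depends on scaling, since the lowess correction gave 146 higher and 79 lower and a repeated quantile normalization 116 higher and 106 lower. Over the 3 comparisons, 40 of 102 list medians lay outside the central 95% of random lists. By chance 5.10 would, if the genes of a list varied independently of each other, as randomly drawn genes do. Whether the genes of these lists do so was not tested, and the lists share genes and arrays.

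Finally, each array was set against both others. WT stood at least 2-fold apart from both mutants for 139 genes, RQ from both others for 93 and MI for 90. WT was above both mutants for 124 of its genes, led by Cubn, Srgn, Lama1, Col4a2 and Krt18, and below both for 15, led by Tex19.1, Dppa2, the adenylate kinase Ak4 (8.52 in WT, 9.95 in MI and 10.22 in RQ), the germ cell gene Dazl and Usp17la. RQ was above both others for 80 genes, led by Manba, Tle4, Etv5, Nr0b1 and L1td1, and below both for 13, led by B2m, the galectin Lgals1 (9.96 in WT, 10.96 in MI and 7.96 in RQ), the homeobox gene Rhox5, the fatty acid binding protein Fabp3 and Gja1. MI was above both for 34 genes, led by S100a6, S100a4, Cd44, Anxa1 and Dlk1, and below both for 56, led by Elob, Ifitm1, Twf2, Phc1 and Utf1. The lowess correction gave 113 above and 22 below for WT, 60 and 24 for RQ and 37 and 27 for MI.

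The differences of RQ and MI from WT share the WT array, which alone makes them alike. Across 12041 genes, which are not independent replicates, their Pearson's r was 0.57 and their covariance 0.0952. Shuffling the 3 array labels within each gene, 100 times, gave a mean r of 0.50 (0.46 to 0.54) and a mean covariance of 0.0813. Genes at least 2-fold lower in both mutants numbered 124, against 74.0 on average in shuffled arrays and 4.72 for independent lists, and those at least 2-fold higher in both numbered 15, against 28.3 and 0.892. No gene was 2-fold higher in a mutant and 2-fold lower in the other. Part of the excess may come from the WT array itself, which as a lone control cannot be split, so the overlap is not called a shared effect.

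**Figure D4:**
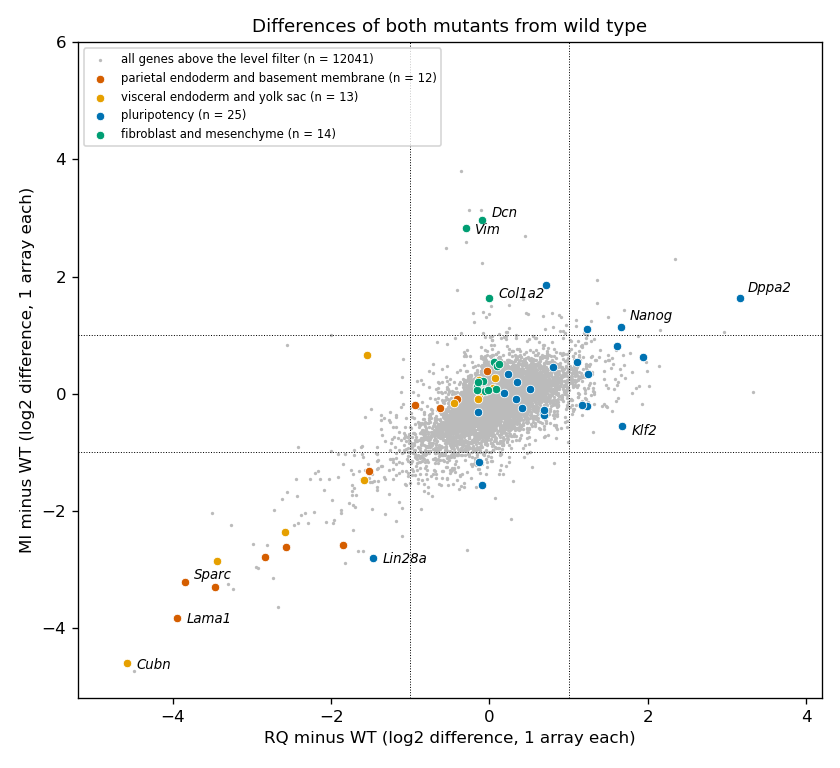
Log2 difference from WT in RQ (x axis) and MI (y axis) for 12041 genes above the level filter in both comparisons (grey), with members of 4 lists coloured and dotted lines at 2-fold. Cubn (-4.58 and -4.60) lies low on both axes, Dppa2 lies highest among pluripotency genes on the x axis (3.17), and Dcn (2.96) lies high on the y axis only.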

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

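All tests of explanations in this part were chosen after the results were seen, except those of level-dependent scaling, which were written before the corrected values were computed. Of the genes named, several differed from WT in opposite directions in the mutants by at least 0.5 each, and with 1 array per genotype the difference between the mutants was not tested. Blm of the homologous recombination list was among them, with an RQ minus MI difference of 1.09 (-0.56 in MI against WT). RQ minus MI was -3.03 for Bgn (-0.54 in RQ and 2.48 in MI, each against WT), 2.24 for Klf2 (1.68 and -0.56), 2.003 for Ptch1 (0.81 and -1.19), -3.39 for B2m (-2.56 and 0.84), -3.00 for Lgals1 (-2.003 and 0.999), -2.20 for Rhox5 (-1.54 and 0.66) and 1.96 for Pdk1 (1.30 and -0.65). With the mean of its probe sets the difference of Ptch1 was 0.67, short of 2-fold. Both probe sets of B2m differed in this way, by -3.39 and -2.85 between RQ and MI. Outside the gene measurements, a control probe set for the mouse B1 repeat was higher in MI than in WT by 1.11 and lower in RQ (-0.78), while a probe set for the B2 repeat differed by 0.05 in MI and -0.04 in RQ and another by 0.41 and -0.23. The cause was not tested.

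Genes of the parietal endoderm and basement membrane list, such as Lama1, Sparc and Col4a1, were lower in both mutants. The 7 at least 2-fold lower in each were the same matrix genes, and the other markers of the list did not show such a fall. After the lowess correction for level-dependent array scaling, the list median nearer to 0 in the 2 mutants was still -1.72. That correction could hardly have brought it near 0, since no level range had a median below -0.154 in RQ or -0.3935 in MI. Genes of a given level in general thus did not share the list's medians of -1.68 in RQ and -1.95 in MI. That 7 of 7 genes stayed at least 2-fold lower in each mutant adds little, because they were chosen by that difference. Fewer endodermal cells in the mutant bodies, or a WT culture with more of them, remain open. The number of secreted visceral endoderm transcripts that stood 1 log2 unit above the filter in WT was 0, so that test had nothing to read. The BRCA1 variants are likewise an open explanation, since culture and genotype cannot be told apart with 1 body preparation each.

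Mesenchymal genes, such as S100a6, S100a4, Dcn and Vim, were higher in MI. Level-dependent scaling could not be decided by the test written for it. The genes at least 2-fold above both other arrays had a median lowess-corrected difference from WT of 1.67, but they were chosen by those differences. The median MI minus WT difference per level range was at most 0.10, so correcting for it could hardly bring their median below 2-fold. The fixed fibroblast list had a median of 0.39 against WT, and 0.29 after the correction. Carried-over fibroblasts that express the whole marker list remain open. The median MI minus RQ difference of the 19 members was 0.33, but members near the filter can show little difference. The 7 members above the stricter filter had a median of 1.64, which is the value of Col1a2 and decides nothing. Members such as Dcn pass that filter through MI alone. Without probe sets that can match several transcripts, Col1a2 was at -0.56 for RQ minus MI. The 34 genes above both other arrays would look alike if mesenchymal cells had formed in the MI bodies or had been carried over with little collagen expression. The labels state that feeder cells were removed on gelatin-coated plates, but no value here shows how completely, so these sources and the variant itself cannot be told apart.

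Abundant genes were generally lower on the MI array, by a median of -0.39 at levels of 11 to 12. Degraded RNA as the cause is argued against, since the 3' minus 5' difference of MI exceeded the higher of the other arrays by 0.14 at most. Compression at hybridization or scanning could not be settled. The 7 spike probe sets above a level of 10 lay 0.23 closer to RQ than 316 genes of their level did, and 5.19% of 10000 random sets of 7 such genes lay as close. Those probe sets read only the spiked transcripts bioD and cre. Sets of 7 separate genes therefore do not measure their spread, and this share decides nothing. Against WT, these spikes had medians of -0.68 in MI and -0.54 in RQ, and genes of their level had -0.38 and -0.07. The spikes thus lay further below WT than the genes did in both mutants, and the cause was not tested. The genotype was not tested as a cause of the lower abundant genes on the MI array.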

How the results depend on the processing

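All alternatives here were chosen before the data were examined. No paired analysis was possible because each genotype has 1 array and the labels give no replicate numbers, and for the same reason no array could be left out. Of the alternative values of the counts and the correlation, 62 stayed within 1.5 times the main count or within 0.05 of r and 29 did not. Alternatives were run for the 40 list medians outside the central 95% of random lists, of whose values 216 moved by less than 0.1, 97 by more and 7 changed sign, and of the highest and lowest genes of each comparison, 234 values moved by less than 0.25 and 59 by more, none with a change of sign. Of 95 values of other named list members past 2-fold, 77 stayed past it after the lowess correction, 71 after quantile normalization again and 66 with means of probe sets, and 11 of 88 fell short without shared probe sets. Alternatives were not run for named genes short of 2-fold or named outside these. Leaving out the level filter moved none of the counts. With a limit of 1.5-fold the counts were 844 higher and 531 lower for RQ against WT, 246 and 1028 for MI against WT, 1221 and 198 for RQ against MI, and 564, 494 and 496 genes with RQ, MI and WT apart. With 3-fold they were 34 and 75, 21 and 69, 29 and 20, and 17, 19 and 50. These follow from the limit itself. Quantile normalization again gave 107 higher and 193 lower for MI against WT and 116 and 106 for RQ against MI, and the lowess correction gave 146 higher for RQ against MI. The lowess correction is fitted to the level-dependent shift of the MI array. How much of that shift stays after quantile normalization again was not read by level. Of the 312 genes lower in MI than in WT, 214 were kept after the lowess correction, and of the 253 higher in RQ than in MI, 132. The mean of a gene's probe sets gave 102 higher for RQ against WT, 198 lower for MI against WT, 129 higher and 42 lower for RQ against MI, and 48 and 58 genes with RQ and MI apart; the cause was not tested. The pluripotency median of MI against WT (0.01) became -0.052 with centred arrays, -0.0074 without the filter, -0.036 with the stricter filter and -0.024 with mean probe sets, but 0.16 after the lowess correction and 0.19 after quantile normalization again. The imprinted median of RQ against WT became 0.0265 with the stricter filter and 0.0205 without shared probe sets, and that of the stress list was 0.021 as a mean; the cause was not tested. Detection calls were not used here, so signal over background limits differences below about the level filter of 6.31.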

Other observations

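The tests in this part were chosen after the results were seen, and so were the list of lysosomal genes and the genes named here. Most lysosomal genes read were below WT in both mutants, 28 in RQ and 26 in MI. Of a textbook list of 40 lysosomal enzymes and membrane proteins, 34 could be read, and 11 were at least 2-fold lower in RQ than in WT and 8 in MI. As the list was written after the values were seen, its percentiles are a description only, and both differences share the WT array. The list's median difference was -0.79 in RQ and -0.78 in MI, both at percentile 0 of 10000 level-matched lists, and -0.79 and -0.53 after the lowess correction. Among them, the protective protein Ctsa read 9.95 in WT, 7.70 in MI and 7.48 in RQ, the cathepsin Ctsh 8.64, 6.43 and 6.36, Ctsz 10.15, 8.42 and 8.41, and Hexa, a subunit of hexosaminidase A, 10.19, 8.57 and 8.48. In RQ 6 members were above 0 and in MI 8, among them Arsb in MI (0.75). The largest exception was Manba, which was 9.88 in RQ against 6.55 in WT and 6.57 in MI, on the only probe set of the gene. Endocytic receptors that deliver cargo to lysosomes, Cubn and Lrp2, were lower on the same arrays.

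Genes related to Eif2s3y and B2m, which are given above with their lists, read near or below the level filter. Eif2s3y, a Y-linked gene, read 8.56 in WT, 6.31 in MI and 5.30 in RQ, while the 3 probe sets of Kdm5d, also Y-linked, lay below the filter on each array, WT included. B2m was 7.15 in RQ against 9.70 in WT and 10.54 in MI, while the MHC class I heavy chain gene H2-K1 lay at 6.96 in WT, 7.04 in MI and 6.88 in RQ.

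A hypothesis is that the RQ bodies held a higher share of undifferentiated cells, which may raise pluripotency genes together. The 8 members of the list with a mean level of 10 or more had a median RQ minus WT difference of 0.74, with 6 above 0 and 2 below, and a lower quartile of 0.27. The spread leaves the hypothesis open, because a higher share would raise Pou5f1 (-0.14) and Dppa5a (-0.15) too unless the other cells expressed them about as much.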
